A study of Danio rerio with 10 samples.

How the data were processed

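RNA was sequenced from pooled whole zebrafish at 3.3 and 96 hpf, with 3 control and 3 BaP libraries at the earlier age and 2 of each at the later. Libraries were made with TruSeq kits and read on a HiSeq2000, per the labels. The submitters' processing notes name TopHat, Partek, edgeR and the genome build Zv9, without versions and without saying what each did. There are 8 deposited tables, for genes and for transcripts, under Ensembl and RefSeq annotation, at each age. Per the file headers and annotation column they use Ensembl release 70 or RefSeq transcripts.

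The deposited values are CPM, scaled by the authors so that each column of a table has the same total, without correction for gene length. This was read from the values themselves, since the files are named as counts. Every listed gene is above 1 CPM in at least 3 libraries at 3.3 hpf or at least 2 libraries at 96 hpf, so low genes had been removed before deposit. Values in a library step by a constant amount, which gives the CPM of 1 read and from it the reads assigned to the listed features, used here as the depth. In the Ensembl tables of genes, between 35.7% and 40.4% of values at 3.3 hpf and between 51.5% and 65.3% at 96 hpf were whole multiples of that step, within a tolerance of 0.05 reads. Whole reads could not be recovered, so no test on counts was run. Values under 1 read point to reads split between features, and how the authors split them is not recorded. No mitochondrially encoded gene is listed, and 0 columns were left unmapped.

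The plan written before the data were examined used a quasi-likelihood test on counts. It was replaced by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the spread on expression) because the values are CPM. The test ran on log2 of TMM-scaled CPM plus a pseudocount of 0.5, with all listed genes and the group as the only term. TMM factors were computed anew, trimming 30% of log ratios and 5% of average levels, and ranged from 0.964 to 1.03 at 3.3 hpf and from 0.941 to 1.07 at 96 hpf. The planned expression filter was not applied, and the pseudocount took the place of a prior count of 2. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, at a threshold of 0.05. The Ensembl gene table was the main one. Each BaP comparison used the libraries of its age. The difference between ages was tested as an interaction in 1 fit of all 10 libraries, on genes listed in both tables. The comparison of control ages that had also been planned was not tested, because the tables were scaled separately.

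There were 32 gene lists, fixed before the data were examined. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Members were matched by symbol, and older names through the names of a current zebrafish reference, from which no coordinates were used. The ribosomal list was written as a symbol prefix that also takes in kinases and a binding protein, and these were excluded. Members were also adjusted over their own list alone, with no adjustment across lists. Genes named in the text follow a rule fixed at the start, with exceptions given below. It takes every measured AhR target and the 7 highest and 7 lowest called genes whose groups do not overlap, with average log2 CPM above 1 and a symbol that is not a clone name. It adds the 3 members with the smallest p of each called list, or of the 4 lists with the smallest p, and the 5 genes with the smallest p for the difference between ages. For the levels by age it takes the 2 most abundant members of 5 lists. Counts of called genes of 5 or fewer are named in full. Further called genes and list members, such as gstp2, txn and hspa5, lie outside this rule and were named because they passed a threshold.

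The gene test was tested on simulated data with means and spreads taken from these libraries, 5 tables per age with 200 changed genes. At 3.3 hpf 6.30% of its calls were false, and at 96 hpf 12.4%. Noise was drawn independently for each gene, and the lowest genes were left unchanged. Counting noise was drawn on top of spreads that already held it, so the simulated spread of low genes need not match the real one. Shifts that many genes of a library share were not simulated, so these shares need not hold for the real libraries. Alternatives written at the start were median-ratio (RLE) scaling, a stricter filter of 50 estimated reads in every library of a group, the RefSeq and transcript tables, a replicate block, all 10 libraries in 1 fit, camera with an estimated correlation, the fry test and each library left out. Alternatives added after the values were seen were other pseudocounts, CPM as deposited, a robust and a trend-free spread, the early zygotic mean as a covariate, a crossed pairing and the ribosomal list by its prefix.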

Results

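The data were RNA sequencing profiles of pooled whole zebrafish of the AB line at 2 ages. At 3.3 hours post fertilization (hpf) the embryo is a blastula that relies largely on RNA laid down by the mother. At 96 hpf it is a larva with a working liver, gut, eyes and circulation. Animals exposed to 50 µg/L benzo[a]pyrene (BaP), a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor (AhR), were compared with controls, which are labelled only with a volume of 0.1 mL/L. There were 3 control and 3 BaP libraries at 3.3 hpf and 2 of each at 96 hpf. The deposited Ensembl tables gave expression in CPM, reads of a gene scaled to a fixed total per library, for 14236 genes at 3.3 hpf and 18910 genes at 96 hpf. The value of 1 read in CPM put the reads assigned to listed genes at 17.5 to 22.2 M per library at 3.3 hpf. At 96 hpf it put them at 13.2 to 17.7 M, so a gene at 1 CPM rested on as few as 13.2 reads. The labels do not say that replicates came from separate clutches, so p-values of the gene tests measure only the spread between these samples, which may be technical. Camera at its preset correlation weighs a list's genes against the other genes, so its p-values do not measure how far libraries vary. Values are scaled CPM, as mean ± SD over the libraries of a group. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes.

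The controls of both ages gave the background for the comparisons. At 3.3 hpf the maternal transcript ccnb1, which encodes the mitotic cyclin B1, stood at 1596 ± 152 CPM (n = 3), against 25.0 ± 1.97 CPM (n = 2) in 96 hpf controls. The maternal zinc finger gene cth1 stood at 1517 ± 289 CPM (n = 3) at 3.3 hpf and was not listed at 96 hpf. Of the early zygotic list, apoeb stood at 17.7 ± 23.6 CPM in 3.3 hpf controls and 765 ± 9.96 CPM in 96 hpf controls. The Nodal pathway gene foxh1, on the same list, stood at 259 ± 6.75 and 1.55 ± 0.39 CPM. Unlike apoeb it varied little between the 3.3 hpf controls, so its place on the list does not show that its RNA was zygotic. The 96 hpf controls held high levels of differentiated tissue genes. The actin gene actc1b stood at 23988 ± 729 CPM and the fast muscle myosin myhz1.1 at 14662 ± 598 CPM (n = 2). The lens crystallins crybb1 and crybb1l2 stood at 1385 ± 141 and 1118 ± 138 CPM, and the globins hbae3 and hbbe1.1 at 912 ± 334 and 812 ± 191 CPM. These levels come from tables that were normalised separately, so they stand side by side and the ages were not tested against each other.

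The first comparison asked which transcripts differed between BaP-exposed and control embryos at 3.3 hpf. No gene was called, and the AhR targets lay within the spread between replicates. The AhR-induced cytochrome P450 gene cyp1a was near the detection limit in both groups, at 1.42 ± 0.52 CPM in controls and 1.40 ± 0.52 CPM in BaP embryos (n = 3). Its log2 difference was -0.01 with a standard error of 0.38. The other 5 measured AhR targets had log2 differences of -0.12 (cyp1d1), -0.25 (ahrrb), -0.17 (tiparp), -0.30 (foxq1b) and -0.32 (nqo1, a quinone reductase). The mean CPM of cyp1d1 went the other way, from 4.60 ± 3.02 in controls to 6.25 ± 5.24 in BaP embryos (n = 3), since BaP replicate 3 stood at 0.27 CPM and weighs more on the log scale. None of the 6 was called over all genes or adjusted over the list alone. Single libraries set the sign of 4 of these differences. Leaving out 1 library moved cyp1a between -0.26 and 0.24, cyp1d1 between -0.79 and 1.1 and foxq1b between -0.92 and 0.43, and tiparp reached 0.01 without BaP replicate 1.

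In limma over 14236 genes at 3.3 hpf, 0 genes passed a Benjamini-Hochberg adjusted p of 0.05 and the smallest adjusted p was 0.907. An unadjusted p under 0.05 was found for 700 genes, where chance gives 712, with 389 of them higher and 311 lower in BaP embryos. Groups did not overlap in 11.5% of genes, where chance gives 10%. In simulated tables with independent noise per gene the test called 44.6% of genes changed 2-fold and 86.2% of genes changed 4-fold. Shifts shared by the genes of a library were not simulated. Without BaP replicate 2, 1 gene was called, the kynurenine aminotransferase gene CCBL2 (1 of 4), which is named after its values were seen. It was listed at 15.7, 22.0 and 13.2 CPM in the controls, at 12.5 CPM in BaP replicate 2 and at effectively 0 in the other two BaP libraries. Its limma adjusted p was 0.907 over all 6 libraries (log2 -3.53) and 0.0414 without BaP replicate 2 (log2 -5.10).

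Of the 26 gene lists with at least 5 measured members at 3.3 hpf, 1 was called. Ribosomal protein genes were lower in BaP embryos by a median log2 difference of -0.15, with 76 of 84 members below control (camera adjusted p = 1.21e-06). The call was lost in camera when the correlation was estimated from the data (adjusted p = 0.716 with an estimated correlation). That version has little power at 3 libraries per group. Relative to the control mean, the median member lay at 0.17, 0.05 and -0.19 in controls and at -0.02, -0.33 and -0.09 in BaP replicates 1, 2 and 3, so only BaP replicate 2 lay below every control. It was also lost without control replicate 1 (adjusted p = 0.0973) and without BaP replicate 2 (adjusted p = 0.216). No member passed the gene test over all genes or adjusted over the list alone. The members with the smallest p were rpl39, at 64.2 ± 11.4 CPM in controls and 48.5 ± 4.50 CPM in BaP embryos (log2 -0.39, n = 3), rplp1 (log2 -0.54) and rpl13a (log2 -0.47). Next by camera p came maternal and oocyte genes (median -0.16, adjusted p = 0.0678), Nrf2 and antioxidant genes (median -0.24, adjusted p = 0.13) and DNA repair genes (median -0.09, adjusted p = 0.150). In the other lists the camera adjusted p ran from 0.158 for circadian clock genes to 0.882 for liver genes. Members adjusted over the list alone were not adjusted across the 26 lists, so a single pass can arise by chance. In the 26 lists 1 gene passed, the endoplasmic reticulum chaperone gene hspa5 of the heat shock list. It stood at 753 ± 64.6 CPM in controls and 446 ± 87.8 CPM in BaP embryos (log2 -0.77, n = 3), with a limma adjusted p of 0.0186 over the list alone and 0.907 over all genes.

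The libraries at 3.3 hpf differed widely in how much early zygotic transcript they held, and did so within both groups. The mean of the 35 measured early zygotic genes, as a log2 deviation from the mean of the 6 libraries, was 1.2, -1.52 and -0.39 in control replicates 1, 2 and 3. In BaP replicates 1, 2 and 3 it was -1.38, 2.07 and 0.01. The members with the widest spread, chosen after their values were seen, show its size. The apelin receptor gene aplnrb stood at 36.0, 0.06 and 1.47 CPM in the controls and 0.15, 142 and 4.79 CPM in the BaP libraries. The mesoderm gene tbx16 was listed at 0 CPM in control replicate 3 and BaP replicate 1 and at 99.3 CPM in BaP replicate 2. The maternal list moved the other way by less, at -0.16, 0.30 and 0.01 in controls and 0.09, -0.13 and -0.11 in BaP libraries. Over the 6 libraries the list means had a Pearson r of -0.84 (two-sided exact permutation p = 0.0292, adjusted p = 0.0583 over 2 relations). Spearman's rho was -0.94 (two-sided exact permutation p = 0.0167, adjusted p = 0.0333). Without control replicate 1 and BaP replicate 2, the libraries farthest from the median, r was -0.90 over the 4 left. Between treatments the early zygotic list was not called (camera adjusted p = 0.556), with 24 of 35 members above control.

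**Figure D1:**
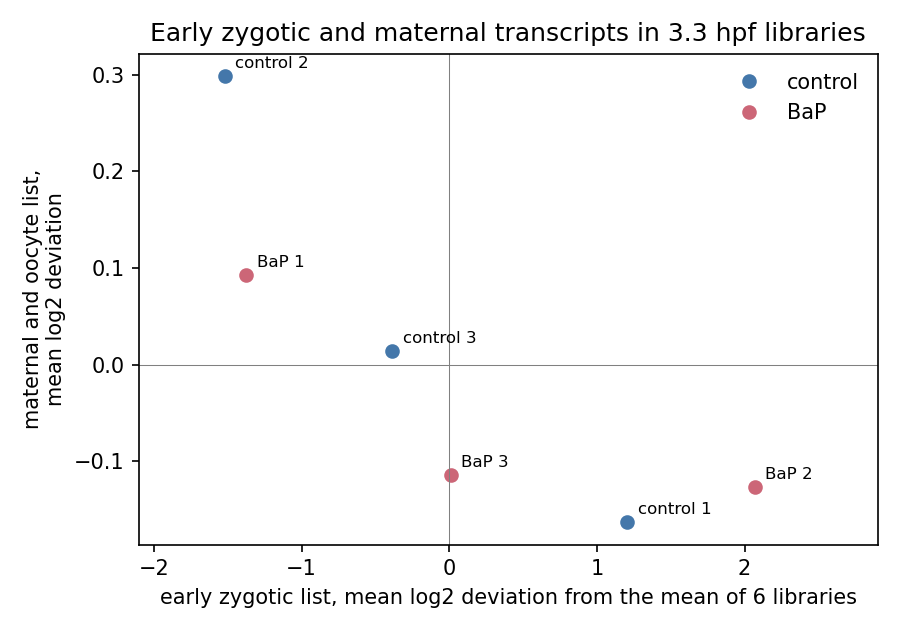
Mean log2 deviation of the early zygotic list (x axis) against that of the maternal and oocyte list (y axis) in each of the 6 libraries at 3.3 hpf, with control libraries as blue and BaP libraries as red points. Points of both groups spread along the x axis, from -1.52 to 1.2 in controls and from -1.38 to 2.07 in BaP libraries, and libraries with more early zygotic transcript lie lower on the y axis.

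The second comparison asked the same of larvae at 96 hpf, where AhR targets rose. The cyp1a transcript went from 15.8 ± 0.30 CPM in controls to 817 ± 52.96 CPM in BaP larvae (n = 2), 50.0-fold on the tested scale (log2 5.64, SE 0.12, limma adjusted p = 7.45e-07). The related cytochrome P450 genes cyp1b1, cyp1c1 and cyp1c2 rose by log2 3.35, 3.06 and 1.87. The forkhead genes foxq1a and foxq1b rose by 2.17 and 1.44, and the sulfotransferase gene sult6b1 by 1.87. These 7 of the 11 measured AhR targets were called over all genes, and 10 of the 11 were higher adjusted over the list alone. The 4 not called over all genes were ugt1ab, a UDP-glucuronosyltransferase gene, at log2 0.71, nqo1 at 0.62, tiparp at 0.54 and cyp1d1 at 0.05. The cyp1d1 difference turned negative without BaP replicate 2 (-0.18), without control replicate 1 (-0.04) and on CPM as deposited (-0.04). Over the alternatives ugt1ab ran from a log2 difference of -0.54 in the RefSeq gene table to 1.06 without BaP replicate 1. Reads could be split between the close paralogs cyp1c1 and cyp1c2. As a list the AhR targets had a median log2 fold change of 1.87 (camera adjusted p = 3.40e-18, and adjusted p = 0.663 with an estimated correlation).

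**Figure D2:**
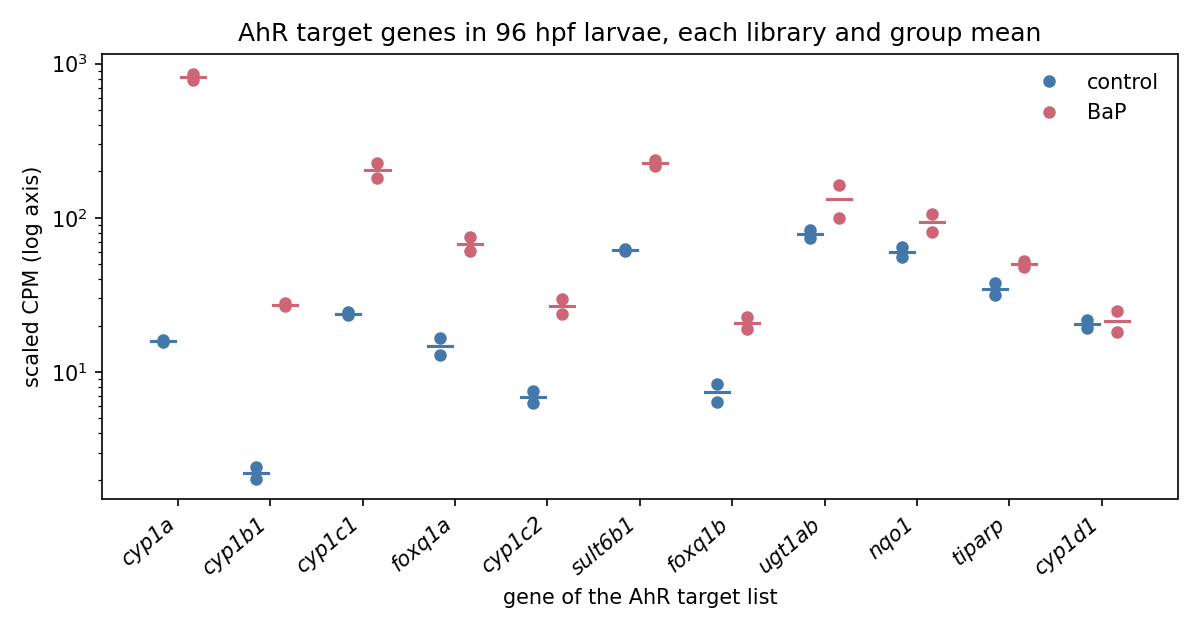
Scaled CPM (log axis) of the 11 measured AhR target genes in each 96 hpf library, with control points in blue, BaP points in red and a line at each group mean (n = 2). The cyp1a points lie at 15.6 and 16.0 CPM in controls and at 779 and 854 CPM in BaP larvae, and cyp1d1 is the only gene of the 11 whose groups overlap.

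In all, 80 of 18910 genes passed limma's adjusted p of 0.05 at 96 hpf, 72 higher and 8 lower in BaP larvae. The excess of higher genes did not extend to the 2980 genes with an unadjusted p under 0.05, of which 1401 were higher and 1579 lower. All 80 had groups that did not overlap, as did 50.4% of all genes, where chance gives 33.3%. After the cyp1 family the highest fold change was that of the fructose transporter gene slc2a5 (log2 2.87, from 0.31 ± 0.22 to 5.81 ± 3.59 CPM, n = 2). The cytochrome P450 gene cyp2x7 followed at log2 2.80, from 0.50 ± 0.17 to 6.56 ± 1.88 CPM. The prostaglandin reductase gene PTGR1 (2 of 2) rose by 2.70, from 4.42 ± 0.43 to 31.6 ± 5.89 CPM, and LRAT, which esterifies retinol, by 2.56, from 0.78 ± 0.45 to 6.90 ± 1.77 CPM. The called entries CABZ01045617.2 and si:ch211-162i8.3, which have clone names, had log2 -3.39 and -2.36. Among called genes with other symbols and an average log2 CPM above 1, the lowest were the ribosomal RNA entry 5_8S_rRNA (log2 -2.39), the collagen prolyl hydroxylase gene p4ha1a (-1.61), the collagen gene col12a1 (-1.28), the keratin gene krt15 (-1.02), the matrix gene postna (-0.92) and the clock gene per1b (-0.87). Several calls lay close to the threshold. That of slc2a5 (limma adjusted p = 0.0466) was lost with median-ratio scaling, on CPM as deposited, with the stricter filter, with either other pseudocount and with a robust or trend-free spread. Without control replicate 1 the adjusted p was 0.0520 for krt15, 0.131 for postna and 0.0647 for per1b. Without control replicate 2 it was 0.112 for p4ha1a and 0.0545 for per1b.

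The number of genes called at 96 hpf was not stable. It was 129 without control replicate 1, 129 without control replicate 2, 3582 without BaP replicate 1 and 247 without BaP replicate 2, in fits where the lone library left is assumed to vary like the other group. Without BaP replicate 1 the balance turned, with 1590 genes higher and 1992 lower. A spread estimated without a trend on expression left 2 calls, cyp1a and cyp1b1, CPM as deposited left 38, and in the transcript table cyp1a alone was called. In simulated tables with independent noise per gene the test called 63.4% of genes changed 2-fold and 96.6% of genes changed 4-fold, and 12.4% of its calls were false. Shifts shared by the genes of a library were not simulated, so these shares need not hold here. The first principal component held 68.6% of the variance and set BaP replicate 2 (52.9) apart from BaP replicate 1 (4.10) and the controls (-20.7 and -36.3).

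Of 31 gene lists with at least 5 measured members, 16 were called at 96 hpf, 14 higher and 2 lower in BaP larvae. None was called with an estimated correlation (smallest adjusted p = 0.663 with an estimated correlation). That version draws its precision from the number of libraries, so with 2 per group it could hardly call any list. The AhR targets, all 11 above control, had an unadjusted camera p of 0.0427 in it. Its lack of calls, here and for single lists, therefore does not decide whether correlation between genes made the preset calls. The fry test asks whether a list's genes move one way on balance, without comparing them with other genes. It called 2 lists, the AhR targets (adjusted p = 0.0390) and the heat shock genes (adjusted p = 4.82e-04). Some genes, such as rpe65a, rlbp1b, rbp4 and nqo1, belong to more than 1 list.

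The Nrf2 and antioxidant list was called higher in camera (adjusted p = 9.82e-13, and adjusted p = 0.666 with an estimated correlation). Of 25 measured members 23 lay above control (median log2 0.48), 5 were called over all genes and 13 were higher adjusted over the list alone. The peroxiredoxin gene prdx1 went from 31.5 ± 0.53 to 86.2 ± 3.50 CPM (log2 1.44, n = 2) and the glutathione S-transferase gene gstp1 from 256 ± 14.2 to 747 ± 99.8 CPM (log2 1.54). Its near copy gstp2, with which it could share reads, rose by 1.45, the thioredoxin gene txn by 1.1 and the glutathione reductase gene gsr by 0.89. The gsr call was lost without control replicate 1 (adjusted p = 0.0557) and without control replicate 2 (adjusted p = 0.112). Phase II conjugation and transport genes were called higher as a list (camera adjusted p = 9.57e-05, and adjusted p = 0.666 with an estimated correlation), with 26 of 29 members above control (median 0.29). None of them was called over all genes and 1 was higher adjusted over the list alone, the glutathione S-transferase gene gstal, from 120 ± 0.45 to 248 ± 72.9 CPM (log2 1.01, n = 2). The transporter gene abcg2a and the epoxide hydrolase gene ephx1 followed at log2 0.55 and 0.65.

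Heat shock and unfolded protein genes were called higher as a list (camera adjusted p = 4.35e-08, and adjusted p = 0.663 with an estimated correlation). Of 26 members 25 lay above control (median 0.26), 1 was called over all genes and 10 were higher adjusted over the list alone. The called member was hsp70.2, an inducible chaperone gene in a family of similar copies, from 16.4 ± 0.76 to 58.1 ± 17.6 CPM (log2 1.76, n = 2). The co-chaperone gene dnajb1b had log2 1.17 (limma adjusted p = 0.0513), and hsp90aa1.1 had log2 0.84, from 225 ± 22.0 to 402 ± 37.5 CPM. The p53 targets were called higher by a small margin (camera adjusted p = 0.0241, and adjusted p = 0.666 with an estimated correlation), with 15 of 21 members above control (median 0.25). No p53 target passed the gene test over all genes or over the list alone, and gadd45aa (log2 0.78), mdm2 (0.50) and sesn1 (0.34) had the smallest p. The list call was lost without control replicate 2 (adjusted p = 0.0785) and without BaP replicate 1 (adjusted p = 0.123).

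Lists of digestive organ genes were called higher in BaP larvae, with few members called over all genes and higher values in BaP replicate 2. In the exocrine pancreas and intestine list 31 of 34 members lay above control (median 0.70), 4 were called over all genes and 17 were higher adjusted over the list alone. Camera gave an adjusted p of 1.12e-12 (adjusted p = 0.666 with an estimated correlation). The amylase gene zgc:92137 went from 9.25 ± 0.73 to 34.9 ± 7.78 CPM (log2 1.84, n = 2). The amylase gene amy2a rose by 1.08, the chymotrypsin-like gene ctrl by 1.13 and the trypsin gene zgc:66382 by 0.86, the last not called without control replicate 1 (adjusted p = 0.106). Liver genes lay above control in 47 of 48 cases (median 0.47), with 1 called over all genes and 7 higher adjusted over the list alone. Camera gave an adjusted p of 1.68e-10 for them (adjusted p = 0.666 with an estimated correlation). The called gene was cyp3a65, a drug-metabolising cytochrome P450 gene, from 68.2 ± 2.07 to 196 ± 21.5 CPM (log2 1.51, n = 2). The liver fatty acid binding protein gene fabp10a had log2 1.67 (limma adjusted p = 0.0513) and the retinol carrier gene rbp4 had 0.68.

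The complement and acute phase list, also made largely in the liver, was called higher (camera adjusted p = 0.00174, and adjusted p = 0.844 with an estimated correlation), with 21 of 26 members above control (median 0.32). None was called over all genes and 1 was higher adjusted over the list alone, the hepcidin gene hamp2 at log2 2.37. Its value was 1.68 without control replicate 1 and 3.07 without control replicate 2. The genes c8g and socs3a followed at log2 0.91 and 0.35, and c8g ran from 0.47 to 1.35 over the alternative fits. Relative to the control mean, the median gene in control replicates 1 and 2 and BaP replicates 1 and 2 lay at log2 -0.09, 0.09, 0.45 and 0.88 for the pancreas list. For the liver list it lay at 0.12, -0.12, 0.15 and 0.75, so BaP replicate 1 was about level with control replicate 1. For the complement list it lay at 0.18, -0.18, -0.07 and 0.78, so the groups overlap. The complement call was lost without control replicate 2 (adjusted p = 0.0604). Without BaP replicate 2 its direction was reversed (adjusted p = 0.246).

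Genes of retinoid metabolism were called higher as a list (camera adjusted p = 2.15e-04, and adjusted p = 0.666 with an estimated correlation). Of 26 members 21 lay above control (median 0.28), 3 were called over all genes and 6 were higher adjusted over the list alone. The retinoid isomerase gene rpe65a of the visual cycle went from 23.4 ± 2.63 to 128 ± 33.5 CPM (log2 2.4, n = 2). The retinaldehyde carrier gene rlbp1b went from 7.92 ± 1.58 to 41.8 ± 12.6 CPM (log2 2.31). The retinol uptake receptor gene stra6 went from 17.7 ± 0.05 to 35.7 ± 1.29 CPM (log2 0.99), and its call was lost without control replicate 1 (adjusted p = 0.0714) and without control replicate 2 (adjusted p = 0.0701). The phototransduction and retina list was not called (median -0.10, camera adjusted p = 0.635), although 4 of its 46 members were called higher, rpe65a, rlbp1b, rgrb (log2 1.12) and pde6h (1.11). Adjusted over the list alone, 5 were higher, these and rgra (1.15), and 4 lower, saga (-0.68), grk7a (-0.47), guca1a (-1.38) and cnga3a (-0.91).

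Pigment cell genes were called higher as a list (camera adjusted p = 3.39e-04, and adjusted p = 0.666 with an estimated correlation), with 19 of 26 members above control (median 0.41). The member tmem130 was called over all genes (log2 1.49), and 9 were higher and 1, ltk (-0.83), lower adjusted over the list alone. The pteridine synthesis gene gch2 had log2 0.77 and the melanin synthesis gene dct 1.26. The lens list was called with a small shift (median 0.15, camera adjusted p = 0.00138, and adjusted p = 0.844 with an estimated correlation), with 43 of 48 members above control and 0 called over all genes. That call was lost without control replicate 2 (adjusted p = 0.888), and the median member in BaP replicate 1 (0.12) was no higher than in control replicate 1 (0.12). The small heat shock protein gene cryabb (log2 1.86) was higher adjusted over the list alone, and crygm2f (0.71) and BFSP1 (0.35) followed.

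Epidermal genes went both ways among the called members. The keratin gene krt1-19d rose from 42.4 ± 3.75 to 136 ± 2.26 CPM (log2 1.67, n = 2), and krt15 fell from 306 ± 44.3 to 150 ± 7.23 CPM (log2 -1.02). The periplakin gene ppl had log2 0.58. As a list they were called higher (camera adjusted p = 2.15e-04, and adjusted p = 0.804 with an estimated correlation), with 27 of 37 members above control (median 0.28) and 8 higher and 1 lower adjusted over the list alone. Without control replicate 2 the list was not called (adjusted p = 0.0561), and its median member lay at 0.12 in both control replicate 1 and BaP replicate 1. Circadian clock genes were called lower as a list (camera adjusted p = 2.15e-04, and adjusted p = 0.666 with an estimated correlation), with 25 of 34 members below control (median -0.38). The period gene per1b was called over all genes, from 120 ± 0.61 to 65.4 ± 1.27 CPM (log2 -0.87, n = 2), and 8 members were lower and 2, cry2a (0.53) and tefa (0.47), higher adjusted over the list alone. The clock genes per3 and nr1d4a had log2 -1.32 and -1.16.

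Erythroid genes were called lower by a small margin (camera adjusted p = 0.0285, and adjusted p = 0.844 with an estimated correlation), with 16 of 23 members below control (median -0.26). The call was lost without control replicate 1 (adjusted p = 0.652) and without BaP replicate 1 (adjusted p = 0.523). The 1 member called over all genes, the mitochondrial translocator gene tspo, was higher (log2 1.27). The anion exchanger gene slc4a1a (-0.82), the transferrin receptor gene tfr1a (-1.48) and klfd (-1.2) were lower adjusted over the list alone. The median member lay at -0.10 in control replicate 2 and -0.08 in BaP replicate 2, so the groups overlap. Ribosomal protein genes all lay above control (84 of 84, median 0.23, camera adjusted p = 7.38e-08, and adjusted p = 0.844 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.180). The median member lay at 0.15 and -0.15 in controls and 0.11 and 0.36 in BaP replicates 1 and 2, so BaP replicate 1 lay below control replicate 1. No member passed over all genes or over the list alone, and RPL29, RPS27L and rplp2 had the smallest p at log2 0.55, 0.40 and 0.39. The histone list was called higher (13 of 15 members above control, median 0.19, camera adjusted p = 0.0241, and adjusted p = 0.844 with an estimated correlation). It was lost without control replicate 2 (adjusted p = 0.888), without BaP replicate 2 (adjusted p = 0.246) and in the RefSeq table (adjusted p = 0.156). Its median member lay at 0.17 and -0.17 in controls and 0.08 and 0.36 in BaP replicates 1 and 2, so the groups overlap. No histone gene passed, and h2afy, H2AFY2 (1 of 2) and hist2h2l had log2 0.45, 0.29 and 0.35.

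Besides the phototransduction list, 14 lists were not called at 96 hpf. Camera gave an adjusted p of 0.0735 for early zygotic, 0.125 for neural and glia, 0.202 for cholesterol and fatty acid synthesis, 0.202 for cell cycle, 0.261 for maternal and oocyte and 0.273 for cartilage and bone matrix genes. For leukocytes it was 0.311, for DNA methylation and one-carbon genes 0.604, for skeletal muscle 0.635 and for the glucocorticoid and hormone axis 0.673. For DNA repair and for AhR pathway components it was 0.832, and for vitellogenins and steroid synthesis and for cardiac muscle 0.971.

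The third comparison asked whether the effect of BaP differed between the ages, by a test of the difference itself in 1 limma fit of all 10 libraries over the 12800 genes listed in both tables. The effect was higher at 96 hpf for 3 genes and lower for 0. For cyp1a it was log2 5.64 at 96 hpf and -0.01 at 3.3 hpf, a difference of 5.66 (SE 0.45, limma adjusted p = 0.00235). For gstp1 it was 1.54 and -0.20, a difference of 1.74 (SE 0.20, adjusted p = 0.0309). For cyb5a, a cytochrome b5 gene whose product passes electrons to cytochromes P450, it was 1.42 and -0.27, a difference of 1.69 (SE 0.20, adjusted p = 0.0383). Next came per1b with a difference of -1.33 (adjusted p = 0.115) and the plexin gene plxnb3 with -1.89 (adjusted p = 0.119). Of the 80 genes called at 96 hpf, 28 were listed at both ages. The other 52, cyp1b1, cyp1c1, cyp1c2 and foxq1a among them, were listed only at 96 hpf, so their difference was not tested. The count of 3 moved with single libraries. At 96 hpf it was 0 without BaP replicate 2, 86 without BaP replicate 1 (12 higher at 96 hpf and 74 lower) and 1, cyp1a, without either control. At 3.3 hpf it was 1, again cyp1a, without control replicate 2 or BaP replicate 3. It was 2 in the other fits at 3.3 hpf, where cyp1a was joined by cyb5a without control replicate 1, by gstp1 without control replicate 3, by per1b (-1.45) without BaP replicate 1 and by CCBL2 (1 of 4) (4.59) without BaP replicate 2. A spread estimated without a trend left cyp1a alone, and a replicate block within age left 0 genes.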

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

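The interaction test of the first paragraph was planned, and the search of the RefSeq table for symbols missing from the Ensembl table was chosen after the data were seen. The effect of BaP differed between ages for 3 genes, which is what brings them here. The log2 effect at 96 hpf exceeded that at 3.3 hpf by 5.66 for cyp1a (limma adjusted p = 0.00235), 1.74 for gstp1 (adjusted p = 0.0309) and 1.69 for cyb5a (adjusted p = 0.0383). At 96 hpf both BaP libraries lay above both controls for each of the 3, which are among the 80 genes called there. Groups did not overlap for any of those 80, nor for 50.4% of all genes, so this adds little. Leaving out BaP replicate 2 at 96 hpf ended all 3 calls (adjusted p = 0.0717, 0.299 and 0.442) while the differences stayed at 5.59, 1.6 and 1.59. Without either 96 hpf control, gstp1 (0.217 and 0.359) and cyb5a (0.321 and 0.415) were not called. At 3.3 hpf gstp1 was not called without control replicate 1 or 2 or any of the BaP libraries (adjusted p from 0.0510 to 0.147), and cyb5a without control replicate 2 or 3 or any of the BaP libraries (0.0552 to 0.16). The age of the fish, the time since exposure began and any batch between the ages are confounded in this design, so the source of the difference was not tested.

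The RefSeq gene table at 96 hpf holds signal under symbols that the Ensembl table does not list. It gave 67 called genes, of which 14 have a symbol absent from the Ensembl table and 9 of those carry clone names. Genes were matched by symbol only, so some of the 14 can stand in the Ensembl table under another name. The 5 without clone names all rose in both BaP libraries. The AhR repressor gene ahrra, a member of the AhR target list, went from 0.64 ± 0.27 to 14.0 ± 2.26 CPM (log2 3.67, limma adjusted p = 0.00186, n = 2). The glucuronosyltransferase gene ugt1b1 went from 31.7 ± 1.90 to 94.4 ± 13.8 CPM (log2 1.56, adjusted p = 0.00362) and the chaperone gene hsp70 from 46.1 ± 1.5 to 136 ± 52.3 CPM (log2 1.5, adjusted p = 0.0393). The interferon-induced gene ifitm1 went from 29.8 ± 1.14 to 70.4 ± 10.02 CPM (log2 1.22, adjusted p = 0.0136) and the paraoxonase gene pon1 from 11.6 ± 2.00 to 26.7 ± 2.15 CPM (log2 1.17, adjusted p = 0.0490). The Ensembl entry IFITM10 went from 24.9 ± 1.03 to 60.7 ± 9.68 CPM (log2 1.26, adjusted p = 0.0191), much like ifitm1, so the 2 symbols can stand for the same gene. The genes ugt1b1 and hsp70 belong to families of similar copies, and how reads were split between them is not recorded. No explanation was tested for these genes. Groups of 2 or 3 libraries are too small for a test of single outlying libraries.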

How the results depend on the processing

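Other pseudocounts, CPM as deposited, a robust or trend-free spread, the early zygotic covariate, the crossed pairing and the ribosomal list by prefix were chosen after the results were seen, and the other alternatives were planned. DESeq2, the edgeR exact test and an analysis without a filter were not run, since the files hold CPM already filtered by the authors, and the control ages were not compared. At 96 hpf the 80 genes became 155 with the replicate block (79 of the 80 kept) and 1 (cyp1a) in the transcript table. They became 38 on CPM as deposited and 2 (cyp1a and cyp1b1) with a spread without trend. With all 10 libraries in one fit 3 were called (cyp1a, gstp1 and cyb5a), but that fit held only 28 of the 80. The other 52 are listed at 96 hpf alone and were not tested in it. Leave-one-out fits, where a lone library is assumed to vary like the other groups, gave 129 to 3582. Of the 80 genes, 65 were kept without control replicate 1, 69 without control replicate 2 and all 80 without either BaP library. Counts within 1.5 times were 76 with RLE factors, 75 with the stricter filter, 70 and 87 with pseudocounts 0.1 and 2 and 76 with a robust spread. The RefSeq table, which has 10072 genes in common with the Ensembl table by symbol, gave 67, also within 1.5 times (47 shared). The 16 lists became 0 with an estimated correlation and 2 with fry, and 11 to 17 in leave-one-out fits. At 3.3 hpf the gene count was 0 in every alternative run, except 0 to 1 in leave-one-out fits. The 1 list became 3 in the RefSeq table, 0 with an estimated correlation, 0 with fry (adjusted p = 0.732) and 0 to 3 in leave-one-out fits. The 3 genes that differed between ages became 0 with the replicate block within age, 1 (cyp1a) with a spread without trend and 0 to 86 in leave-one-out fits. The causes were not tested.

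Replicate numbers are shared between groups, but deviations from the group means correlated at -0.44, -0.43 and -0.01 for numbers 1, 2 and 3 at 3.3 hpf and -0.26 at 96 hpf. These values gave no sign that the numbers pair the libraries. They cannot exclude it, since 2 libraries per group at 96 hpf give a single value. The replicate block left the list counts at 1 and 16 and could not be fitted in the 3.3 hpf RefSeq table, whose columns carry no numbers. A crossed pairing at 96 hpf gave 2179 genes, 976 higher and 1203 lower.

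Single results that reversed were few. At 3.3 hpf leave-one-out values ran from -0.26 to 0.24 for cyp1a, -0.79 to 1.1 for cyp1d1, -0.29 to 0.0092 for tiparp and -0.92 to 0.43 for foxq1b, and cyp1d1 was 0.094 with pseudocount 2. At 96 hpf cyp1d1 was -0.0024 in the RefSeq table, -0.041 on CPM as deposited and -0.18 to 0.28 in leave-one-out fits, and ugt1ab was -0.54 in the RefSeq table. In leave-one-out fits the complement list ran from an adjusted p of 2.17e-10 to 0.246, reversed at the latter, and it had 0.844 with an estimated correlation and 0.681 with fry. Of 64 named genes at 96 hpf, 63 kept direction and side of the threshold with RLE factors, 52 on CPM as deposited (11 lost), 61 with pseudocount 0.1, 60 with pseudocount 2 and 35 with a spread without trend (29 lost). The median of all genes at 96 hpf was 0.02 with TMM, 0.00 with RLE and -0.07 as deposited. Depth limits low genes most, since 1 CPM is as few as 13.2 reads.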

Other observations

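The limma comparison at 96 hpf and the RefSeq table were planned, while the genes described here and the tests of eye tissue, pigment cells, stage, depth and splits were chosen after the results were seen. Several called genes at 96 hpf lie outside the gene lists. The prostaglandin D synthase gene ptgdsb rose from 203 ± 5.17 to 784 ± 31.0 CPM (log2 1.94, n = 2). The enzyme genes cyb5a, ugt1b4, cbr1l and gsto2 rose by log2 1.42, 1.45, 1.2 and 1.14. The myoglobin gene mb rose from 57.4 ± 7.46 to 132 ± 2.4 CPM (log2 1.2), the methionine sulfoxide reductase gene msrb1a by 0.99 and the organic anion transporter gene slc22a7a by 0.99.

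Within lists that were not called at 96 hpf, some members passed when adjusted over their own list, though not over all genes. Among AhR pathway components the receptor gene ahr2 was higher (log2 0.53, limma adjusted p over the list = 0.0296) and ptges3a was higher (0.33), while arnt (-0.92), ahr1b (-0.64) and arnt2 (-0.37) were lower. In the DNA methylation list tet3 (-0.92) and tet1 (-1.29) were lower and gnmt (0.75) higher. In the cartilage list col11a1b (-0.65), hapln1a (-0.51) and sox9b (-0.98) were lower and spp1 (1.0) and matn3a (0.69) higher. Besides these and the phototransduction list, members passed for maternal and oocyte genes (2 higher, 1 lower). They also passed for vitellogenins and steroid synthesis (1 higher, 1 lower) and for the glucocorticoid and hormone axis (1 higher).

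The gene mpx showed that annotation matters for single genes. In the RefSeq table it went from 20.5 ± 3.96 to 143 ± 55.8 CPM (log2 2.73, limma adjusted p = 0.00306), and in the Ensembl table from 15.9 ± 4.34 to 15.7 ± 4.14 CPM (log2 -0.02, adjusted p = 0.981). Of 10072 genes listed in both, 57 were called in either and 47 in both, and 2 of the 57 differed by over 1 on the log2 scale. The other was mgrn1a, at 0.03 and 1.37.

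A first pattern was noticed among the genes called at 96 hpf, of which 8 act in the eye (rpe65a, rlbp1b, rdh5, LRAT, rgrb, irbp, stra6 and pde6h). They were picked because they were called, so their median log2 fold change of 1.65 (quartiles 1.12 and 2.33, lowest 0.99) follows from the choice, and the fixed phototransduction and retina list was not called (camera adjusted p = 0.635). A larger share of eye tissue in the BaP pools would raise photoreceptor genes alike. The median of all 46 measured members of the phototransduction list was -0.10 with quartiles of -0.29 and 0.12. The list as a whole did not rise, which argues against a larger share of eye tissue as the whole cause. A larger share of pigment cells could raise genes of the pigment epithelium. The 8 melanin synthesis genes had a median of 0.84 with quartiles of 0.55 and 1.06, against 0.13 for the other 18 pigment cell genes. All 8 lay above control, but 0 were called over all genes, and groups overlapped for tyr and slc24a5. Of the other 18 genes 1 was called. A change in pigment cell share and a change of transcription within those cells cannot be told apart, because whole larvae were pooled. A direct response of these genes to BaP stays open and was not tested.

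A second pattern is the spread of early zygotic transcripts at 3.3 hpf. Depth is argued against by BaP replicates 1 and 2, which differ by 3.44 in the early zygotic mean at a depth ratio of 1.04. Pools collected at slightly different points around the onset of zygotic transcription may explain the spread. The Pearson correlation of early zygotic with maternal transcript over the 6 libraries was -0.84 (two-sided exact permutation p = 0.0292, adjusted p = 0.0583). A negative correlation was assumed for that reading after the values were seen. The Pearson value misses the threshold after adjustment, while Spearman's rho was -0.94 (exact permutation adjusted p = 0.0333). Collection times are not in the labels, so this stays a hypothesis. With the early zygotic mean as a covariate 0 genes and 1 list were called at 3.3 hpf.

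The 6 libraries at 3.3 hpf were also split in all 10 ways into 3 against 3. The real split gave 0 genes (highest other 2), which no split can fall below, so for genes the comparison says nothing. It gave 1 list (highest other 4). Each of the 10 splits gave at least as many, so the count of lists does not set the real split apart. In any case 10 splits are too few for a share under 0.05.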
